A study of Mus musculus with 4 samples.

How the data were processed

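Single-cell RNA sequencing was analysed from 4 mouse mammary tumour libraries, 1 library per group, made with the 10x Genomics 3' v2 kit, per the labels' protocols. The deposited values were raw counts of unique molecular identifiers (UMIs) per gene and cell barcode. Each matrix was written by Cell Ranger 3.0.2, per the file headers, against the mouse genome mm10, per the submitters' processing notes. The feature table held 31054 features, of which 31053 had Ensembl identifiers and 1, NeomycinResistanceGene, had been added. The lowest barcode total was between 500 and 503 UMIs in each library, so the deposited matrices held only barcodes with at least 500 UMIs. No further processing by the submitters is given in the sources used here.

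Cells with fewer than 200 detected genes were removed, which took 107 and 307 barcodes from the treated and untreated T11-Apobec libraries and 8 and 23 from the treated and untreated KPB25Luv libraries. Cells with more than 10% mitochondrial UMIs were removed next, 266 and 676 in T11-Apobec and 228 and 275 in KPB25Luv. Doublets were scored per library with Scrublet as run by scanpy 1.11.5. The tool's own threshold marked 2 barcodes in the treated T11-Apobec library and 3 in the treated KPB25Luv library, which was taken as a failure. Therefore, after the data were seen, the highest scores were removed at a rate of 0.8% per 1000 barcodes, which took 299, 875, 232 and 343 cells in the order treated and untreated T11-Apobec, treated and untreated KPB25Luv. The removal left 5832, 9446, 5041 and 6132 cells in the same order.

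The 4 libraries were clustered together without integration. Counts were normalised to 10000 UMIs per cell and log-transformed. The 2000 most variable genes were used, leaving out immunoglobulin and T cell receptor segments, mitochondrial genes and ribosomal protein genes. Clusters came from 30 principal components, 15 neighbours and the Leiden method at resolution 1. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9 and matplotlib 3.10.9. Clusters were named from marker genes of 18 cell classes fixed before the files were opened. A marker counted as raised at 2-fold over the other cells with detection in at least 10% of the cluster, and a name needed at least 3 raised markers. A class was compared by name only if no cluster in it held more markers of another class than of its own among its 10 leading genes by fold. Cluster 5 carried 17 of 22 macrophage/monocyte markers, but its 10 leading genes held 1 fibroblast marker, C3, and no marker of its own class. Clusters 5, 7, 12 and 18, in which macrophage/monocyte markers were raised, are therefore given by number. In KPB25Luv the lists meant for tumour cells were read in the epithelial class, a choice made after seeing that 0 treated and 7 untreated cells fell in the tumour/mesenchymal class.

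Shares of cells are given with exact Clopper-Pearson 95% intervals. Immune classes are shares of the cells in immune classes, and other classes are shares of all kept cells. Expression within a class was the sum of UMIs over its cells scaled to the total of the class (CPM), with exact Poisson intervals. The log2 ratio of treated over untreated used 0.5 added counts and an exact conditional 95% interval. Classes were compared where both libraries held at least 50 cells. A total of 29 gene lists with 309 genes was fixed before the files were opened, and 5 of those genes were absent from the feature table. A list's value is the median log2 ratio of its members with at least 10 UMIs in the 2 libraries together. Its interval came from 200 resamplings of the counts, and its percentile from 10000 random lists of the same size matched on expression in 20 bins. A member is called higher or lower at 1.5-fold. Where 1 library had no UMI of a gene, a bound was computed with 3 counts in that library's class. All intervals and bounds cover counting error only, since no group had a replicate, and no p-value was computed.

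The genes named per class were the 4 highest and 4 lowest by the interval end nearest to 0. They needed at least 50 UMIs in the library where the gene was higher, a UMI in at least 5% of that library's cells of the class, and a class CPM of at least 0.5 times the CPM over all its cells. Mitochondrial, ribosomal protein, haemoglobin, sex-specific, immunoglobulin, T cell receptor and histone genes and unnamed gene models were left out. Besides these, 2 to 4 members of each list with the most UMIs or the largest ratio were named, as were the therapy's targets and their ligands. Genes named outside this rule were chosen after their values were seen. T cells were clustered again with the same settings. For shares of T cells with a UMI of a gene, each cell was thinned to 1000 UMIs, and shallower cells were left out. Gene positions were taken by Ensembl identifier from the GENCODE annotation of GRCm38, the assembly of mm10.

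The ratio and list steps were tested on simulated data drawn from the class sums, with 200 genes altered by known folds. The altered genes, the planted list among them, were drawn only from genes well covered in the shallower library. Recovery of genes with few UMIs was therefore not tested. Both simulated libraries were Poisson draws around a shared mean, which is the model that the intervals assume. Spread between animals or cells and shifts in the mix of clusters were thus not tested either. The gene totals below count all genes with at least 10 UMIs in the 2 libraries together, not the altered ones. Intervals excluded no change for 96.9% of the genes altered 2-fold and 100.0% of those altered 4-fold in the T11-Apobec T cells, over 11436 genes. In KPB25Luv T cells the same shares were 99.0% and 100.0% over 12300 genes. In clusters 5, 7, 12 and 18 the shares for 2-fold were 98.1% over 12021 genes in T11-Apobec and 91.2% over 11197 genes in KPB25Luv. A planted list of 15 genes altered 4-fold came out at a median of 2.05 in T11-Apobec T cells and above all 10000 random lists.

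Alternatives covered the filters on genes and mitochondrial UMIs, doublets, the cluster resolution, clustering of each library alone, naming by marker score, the denominator, the scaling of counts, thinning, added counts and the minimum for list members. The cells in sub-sets of clusters and the doublet tool's own threshold were added as alternatives after the data were seen. The H2 and immunoglobulin haplotypes of BALB/c and FVB/NJ differ from those of the reference, so isotypes were compared only within a model.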

Results

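The data compare the cells of triple-negative mammary tumours in mice with and without immune checkpoint inhibitors. Tumour cells of the model T11-Apobec were grown in the mammary gland of BALB/c females and those of KPB25Luv in FVB/NJ females. Treatment was with antibodies against PD1, at 10 mg/kg, and CTLA4, at 100 µg, biweekly from a tumour diameter of 5 mm, and tumours were taken after 7 days. Each of the 4 groups, treated and untreated in each model, was 1 library of dissociated tumour. No group had a replicate, so every comparison is of 2 libraries, and its intervals cover counting error only.

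The treated T11-Apobec library held 6504 barcodes with 47131040 UMIs, and the untreated one 11304 barcodes with 98475778. The treated KPB25Luv library held 5509 barcodes with 30369476 UMIs, and the untreated one 6773 with 87677328. After filtering, 5832 treated and 9446 untreated T11-Apobec cells had medians of 3954 and 7172 UMIs. In KPB25Luv, 5041 treated and 6132 untreated cells had medians of 3732 and 9117 UMIs.

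The first comparison asked which cells and genes differed between treated and untreated T11-Apobec tumours. T cells made up 57.4% (56.0 to 58.8%) of immune cells in the treated library against 10.4% (9.46 to 11.4%) in the untreated one, 5.52-fold higher (4.97 to 6.14). B cells made up 16.05% (15.04 to 17.09%) against 4.52% (3.88 to 5.22%), 3.55-fold higher (3.01 to 4.21). Plasma cells numbered 40 against 1, a log2 ratio of 4.38 (2.38 to 10.28) that was 0.82 when cells were named by marker score. Clusters 5, 7, 12 and 18, in which macrophage/monocyte markers were raised, made up 15.6% (14.6 to 16.6%) in the treated and 68.2% (66.7 to 69.7%) in the untreated library, 4.38-fold higher without treatment (4.04 to 4.75). The tumour/mesenchymal class was 12.4% (11.6 to 13.3%) of all cells against 53.8% (52.8 to 54.8%).

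Among the smaller T11-Apobec classes, neutrophils were 0.893% (0.652 to 1.19%) of treated and 4.36% (3.74 to 5.05%) of untreated immune cells. Plasmacytoid dendritic cells were 1.15% (0.875 to 1.48%) against 0.568% (0.356 to 0.858%), a ratio that turned to a log2 value of -0.03 when cells were named by marker score. Natural killer (NK) cells were 7.95% (7.22 to 8.73%) against 11.8% (10.8 to 12.9%) of immune cells, but over all cells their ratio turned to a log2 value of 0.50. Immune classes were 86.5% (85.5 to 87.3%) of the treated and 41.0% (40.0 to 42.0%) of the untreated cells. Over all cells the log2 ratio was 3.54 for T cells, 2.90 for B cells and -1.06 for clusters 5, 7, 12 and 18, against 2.46, 1.83 and -2.13 over immune cells, and with a floor of 500 genes it was 3.11 for B cells. Endothelial cells were 0.0857% (0.0278 to 0.200%) against 3.44% (3.08 to 3.83%), and 0 treated pericytes stood against 53. The median T cell held 3484 UMIs in the treated and 1348 in the untreated library, and the median B cell 1623 and 858, while cells of clusters 5, 7, 12 and 18 held 8748 and 3930.

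**Figure D1:**
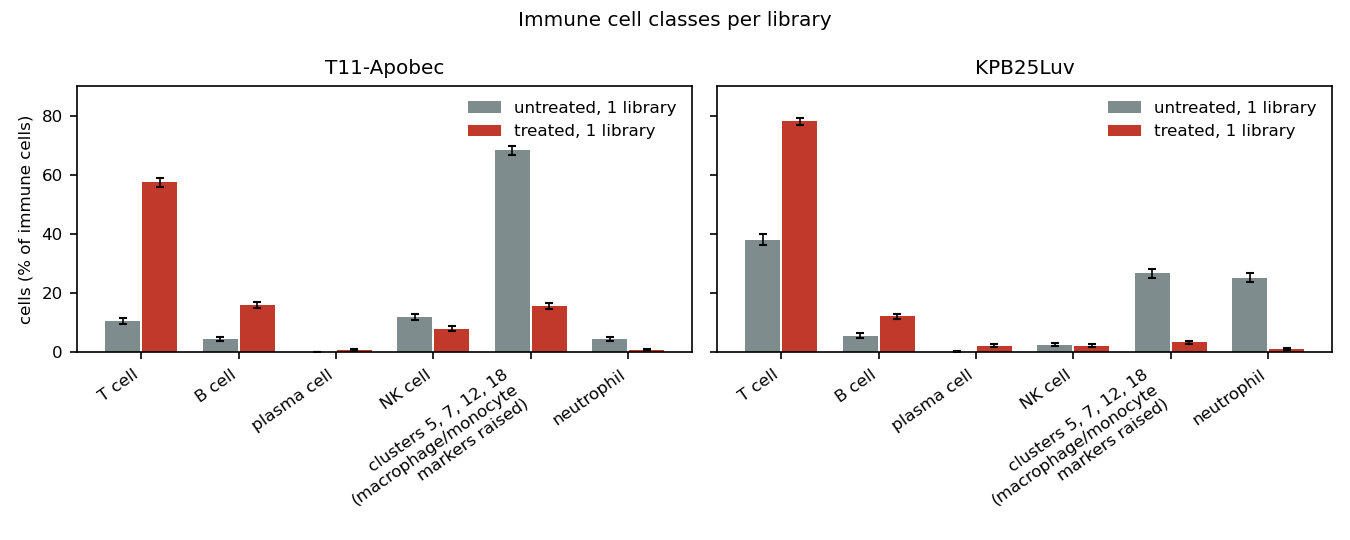
Bars give the share of immune cells (percent, y axis) in 6 classes (x axis) for the untreated and treated library of each model, with exact 95% intervals. T cells reached 57.4% and 78.1% in the treated libraries against 10.4% and 38.1% in the untreated ones.

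In T11-Apobec T cells, Ifitm1, which codes for an interferon-induced membrane protein, stood at 705 CPM in the treated and 20.4 CPM in the untreated library, a log2 ratio of 5.11 (4.36 to 5.98). Ifitm2 was at 347 against 39.3 CPM, and Lgals3, coding for galectin-3, at 998 against 188. Gstm5 was at 36.3 CPM against 0 UMIs, at least 8.31-fold higher. The lowest genes were Dusp1 (log2 ratio -2.32, -2.52 to -2.12), Ccl5 (-1.97, -2.02 to -1.92), Rgs2 (-1.80, -2.10 to -1.48) and Ikzf2 (-1.47, -1.67 to -1.27), the last coding for the regulatory T cell factor Helios. Most treated T cells sat in clusters 2 and 4 (34.2% and 27.4%), and most untreated ones in clusters 3 and 10 (43.4% and 30.02%).

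The cytotoxicity list in T11-Apobec T cells had 8 of 16 measured genes higher and 1 lower, with a median of 0.53 (0.41 to 0.77), above all random lists. With the 3 genes at 0 UMIs in the untreated library set to their bounds, the median was 0.24. Of these 3, Gzmf was at 37.0 CPM, at least 8.46-fold higher. Gzmd was at least 1.18-fold higher and Gzme lay under its floor, so neither is shown to be higher at 1.5-fold. Nkg7 was at 2132 against 2079 CPM, and Ccl5 was lower. The inhibitory receptor and exhaustion list had 0 higher and 6 lower of 10, with a median of -0.92 (-1.03 to -0.55), below all random lists. Pdcd1 was level at 281 CPM in both libraries, and Nr4a2 and Cd160 were lower at -1.43 (-1.88 to -0.96) and -1.25 (-1.80 to -0.67). The regulatory T cell list had 2 higher and 7 lower of 11, with a median of -1.20 (-1.37 to -0.90), below all random lists, and Tnfrsf18 was at 165 against 430 CPM. The naive and memory list had 7 higher and 1 lower of 10, with a median of 0.90 (0.61 to 1.13), and Lef1 was at 135 against 46.6 CPM. The follicular helper list was near level at 0.10 (-0.12 to 0.43; 75.5th percentile), and the activation list was at -0.24 (-0.38 to -0.04; 1 higher and 4 lower of 14), with Nr4a1 at 10.8 against 46.6 CPM. The proliferation list was at 0.51 (0.40 to 0.65), with Stmn1 at 311 against 175 CPM, the interferon-gamma list at -0.12 (-0.28 to 0.19), the type I interferon list at -0.67 (-1.13 to -0.24), and the dissociation stress list at -0.45 (-0.66 to -0.15).

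These T cell medians were not alike in all clusters. In clusters 3 and 10 alone, the naive and memory median was 0.81, while the cytotoxicity median turned to -0.25, the exhaustion median to 0.06, the regulatory median to 0.15, the activation median to 0.29 and the type I interferon median to 0.50. These clusters parted, with exhaustion at 0.45 (0.17 to 0.62) in cluster 3 and -0.99 (-1.67 to -0.27) in cluster 10, regulatory genes at 0.68 and -0.35, and activation genes at 0.84 and -0.41. Naive and memory genes were near level in cluster 3, at 0.02 (-0.25 to 0.53), and higher in cluster 10, at 1.35 (0.92 to 2.25). Within cluster 4, with 793 treated and 60 untreated cells, the type I interferon median was 3.95 (3.50 to 4.57). No bounds were computed within single clusters for genes without a UMI in a library, so the size of this median is uncertain. In T11-Apobec B cells the median of the same list was 0.91, or 0.26 at its bounds. Thinned to 1000 UMIs, the regulatory median was -0.56.

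In T11-Apobec B cells, all in cluster 0, Il4i1 stood at 193 CPM in the treated and 30.1 CPM in the untreated library, a log2 ratio of 2.66 (1.44 to 4.31). It codes for an amino acid oxidase of activated antigen-presenting cells. Samsn1 and Selenow were higher as well, at 2.26 (1.38 to 3.34) and 1.82 (1.13 to 2.61), and Arhgap9 was at least 2.93-fold higher against 0 UMIs. Apoe was at 580 CPM against 4467 CPM in B cells and 9002 against 19321 CPM in clusters 5, 7, 12 and 18, while untreated T and NK cells held 172 and 143 CPM. Zbtb20, Dusp1 and Cxcr4 were lower at -2.26, -1.99 and -1.78. The naive B cell list had 8 of 12 genes higher and 1 lower, with a median of 0.64 (0.36 to 0.83), above all random lists, and Fcer2a at 323 against 108 CPM. The antigen presentation list was at 0.26 (0.19 to 0.36; 96.1st percentile), with Cd74 at 0.73 (0.65 to 0.80). The B cell activation list had 4 higher and 5 lower of 14 at -0.47 (-0.69 to 0.10), Cd83 being at 524 against 199 CPM and Egr1 at 21.4 against 114. The germinal centre list, with 5 of 12 genes measured, was at -0.32 (-1.25 to 0.80), and the plasma cell programme at -0.19 (-0.46 to 0.44). The interferon-gamma list was at 0.73 (0.26 to 1.59), the stress list at -0.48 (-0.73 to -0.28), and 175 untreated B cells with 166091 UMIs limit all of these values.

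In T11-Apobec clusters 5, 7, 12 and 18, Ly6a, which codes for the interferon-inducible surface protein Sca-1, stood at 513 CPM in the treated and 4.20 CPM in the untreated library, a log2 ratio of 6.91 (6.52 to 7.38). Pdcd1lg2, coding for the PD1 ligand PD-L2, was at 38.4 against 0.537 CPM, 6.03 (5.02 to 7.62). Ly6i was at 6.33 (5.39 to 7.77), and Acod1, coding for the enzyme that makes itaconate, at 5.61 (4.93 to 6.52). Lower were Fcrls at 5.39 against 348 CPM, Slco2b1 at -4.75, Tmem119 at -3.24 and Rapsn at -3.19. Treated cells were mostly in cluster 5 (71.5%), and untreated ones mostly in cluster 18 (90.1%).

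The interferon-gamma response list in these T11-Apobec clusters had 16 of 17 measured genes higher and 0 lower, with a median of 2.28 (2.12 to 2.47), above all random lists. Cxcl9, a chemokine that draws T cells through CXCR3, was at 687 against 78.4 CPM, and Gbp2b at 206 against 18.2 CPM. The monocyte list had 7 higher and 0 lower of 10, at 2.11 (1.89 to 2.30), with Ly6c2 at 219 against 16.9 CPM. The major histocompatibility complex (MHC) class II list had 7 higher of 8, at 1.16 (1.15 to 1.17), with Ciita at 115 against 36.9 CPM. The alternative macrophage list was at 0.59 (0.39 to 0.80), with Arg1 at a log2 ratio of 3.08 and Ccl8 at 3.58. The inflammatory list had 3 higher and 5 lower of 11, at -0.56 (-0.69 to -0.43), with Cxcl2 at 128 against 325 CPM and Nos2 at 20.9 against 0.268 CPM (6.02, 4.71 to 8.58). The type I interferon list was at 0.27 (0.12 to 0.38), the complement list at -0.27 (-0.33 to -0.18), the proliferation list at 0.17 (0.07 to 0.21) and the stress list at -0.74 (-0.81 to -0.68). In cluster 12 alone the MHC class II median turned to -0.85, the complement median to 0.53 and the proliferation median to -1.92, while the interferon-gamma median was 3.16, and thinned to 1000 UMIs the proliferation median turned to -0.04. In cluster 18 alone, with 53 treated and 2381 untreated cells, the alternative median turned to -0.67 (-1.56 to -0.40), the proliferation median turned to -0.40 (-0.48 to -0.06), and the monocyte median was 0.02 (-0.68 to 0.28). The interferon-gamma median there was 1.25 (0.97 to 1.54) and the type I interferon median 1.54 (1.39 to 1.86).

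In T11-Apobec tumour/mesenchymal cells, Ubd, coding for an interferon-inducible ubiquitin-like protein, stood at 202 CPM in the treated and 4.20 CPM in the untreated library, a log2 ratio of 5.59 (5.42 to 5.77). H2-DMb1, whose product loads peptides onto MHC class II, was at 128 against 2.28 CPM, 5.80 (5.57 to 6.05). The complement protease gene C1s1 was at 6.46 (5.90 to 7.20) and Apol6 at 6.35 (5.47 to 7.71). Mest (-4.24, -4.95 to -3.63), Ptn (-3.40), Tnni1 (-3.51) and Bmp8a (-3.25) were lower. The tumour interferon-gamma list had 13 of 13 measured genes higher, with a median of 3.15 (3.08 to 3.25), above all random lists, Iigp1 being at 438 against 21.6 CPM and Cxcl9 at 83.1 against 2.98 CPM. The MHC class I list had 13 of 14 higher, at 1.52 (1.49 to 1.55), with H2-D1 at 3003 against 774 CPM and Psmb9 at 308 against 33.8 CPM. The extracellular matrix list had 1 higher and 9 lower of 17, at -0.65 (-0.68 to -0.54), with Col1a1 at 53.1 against 161 CPM. The hypoxia list was at 0.54 (0.48 to 0.56), with Eno1 at 0.98 (0.93 to 1.03), the proliferation list at -0.02 (-0.06 to 0.02), and the stress list at -0.96 (-1.01 to -0.90). Cluster 1 held 74.2% of the treated and 2.24% of the untreated cells, and within it the tumour interferon-gamma median was -0.14 (-0.23 to 0.02). The type I interferon list was at 1.04 (0.92 to 1.19) over the class and turned to -2.22 (-2.45 to -1.98) in cluster 1, with 14 of 16 genes lower. In clusters 14 and 16 together the tumour interferon-gamma median was 1.24. The MHC class I median was smaller within clusters than over the class. It was 0.47 (0.41 to 0.60) in cluster 1, 0.90 (0.83 to 1.04) in cluster 14 and 0.61 (0.53 to 0.87) in cluster 16.

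T11-Apobec epithelial cells, all in cluster 21, were 0.977% (0.741 to 1.26%) of treated and 0.646% (0.494 to 0.829%) of untreated cells. Their extracellular matrix list had 6 of 6 genes lower, with a median of -3.80 (-4.73 to -3.20), and their hypoxia list 12 of 12 lower, at -1.34 (-1.74 to -1.17), beside a stress list at -0.43 (-0.70 to -0.25). Their MHC class I list had 10 of 13 genes higher, at 0.92 (0.65 to 1.01), and their tumour interferon-gamma list 7 of 9 higher, at 1.41 (0.59 to 2.01). The matrix values ran with free RNA, as Col3a1 was at 6.05 against 64.0 CPM in these cells and at 4.92 against 52.4 CPM in T cells, which should lack it. T11-Apobec NK cells were lower for proliferation genes, with 14 of 20 lower and a median of -0.67 (-1.10 to -0.61), and near level for stress at -0.09. Their interferon-gamma list was at 0.68 (0.32 to 0.89), and their type I interferon list at -0.74 (-1.05 to -0.05). Over all T11-Apobec cells, the lymphoid chemokine and cytokine list was at 2.25 (1.91 to 2.47), with Lta at 19.4 against 0.394 CPM, a value that mixes expression with class shares.

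The second comparison asked the same of KPB25Luv tumours. T cells made up 78.1% (76.9 to 79.2%) of immune cells in the treated library against 38.1% (36.4 to 39.8%), 2.05-fold higher (1.92 to 2.19). B cells made up 12.1% (11.2 to 13.1%) against 5.52% (4.74 to 6.38%), 2.20-fold higher (1.85 to 2.62), and plasma cells 2.24% (1.84 to 2.69%) against 0.0963% (0.0199 to 0.281%), 111 cells against 3. Clusters 5, 7, 12 and 18 made up 3.29% (2.81 to 3.82%) against 26.7% (25.1 to 28.3%), 8.11-fold higher without treatment (6.85 to 9.66). Neutrophils made up 1.15% (0.872 to 1.49%) against 25.2% (23.7 to 26.8%), 21.9-fold higher without treatment (16.7 to 29.2). Epithelial cells were 1.37% (1.07 to 1.73%) of treated and 47.0% (45.7 to 48.2%) of untreated cells, 34.3-fold higher without treatment (27.0 to 44.2).

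NK cells in KPB25Luv were 2.16% (1.77 to 2.60%) against 2.60% (2.07 to 3.22%), a difference not detectable at this depth. Dendritic cells were 0.625% (0.425 to 0.886%) against 1.28% (0.919 to 1.74%). Endothelial cells were 0.179% (0.0817 to 0.339%) of all cells against 1.30% (1.04 to 1.62%), a log2 ratio that turned to 0.21 when each library was clustered alone. Fibroblasts numbered 4 against 37, and their ratio turned when doublets were kept, to 0.30 here and to 0.75 in T11-Apobec, where they numbered 4 against 49. Immune classes were 98.4% (98.0 to 98.7%) of the treated and 50.8% (49.6 to 52.1%) of the untreated cells. Over all cells the log2 ratio was 1.99 for T cells, 2.08 for B cells and -2.06 for clusters 5, 7, 12 and 18, against 1.04, 1.13 and -3.02 over immune cells. It was -3.69 for those clusters with up to 20% mitochondrial UMIs, 2.71 against 4.32 for plasma cells named by marker score, and -8.31 against -5.09 for epithelial cells with each library clustered alone. T cell medians were 3979 and 3332 UMIs, B cell medians 2548 and 2003, and those of clusters 5, 7, 12 and 18 were 4310 and 7516.

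In KPB25Luv T cells, Ifitm1 was again higher, at 218 against 20.6 CPM (log2 ratio 3.40, 3.12 to 3.69). The T helper cytokine gene Il4 was at 16.9 against 0.778 CPM (4.37, 3.07 to 6.32), the inhibitory receptor gene Lag3 at 90.02 against 10.1 CPM (3.15, 2.76 to 3.58), and the chemokine gene Ccl4 at 192 against 27.6 CPM (2.80, 2.56 to 3.05). Cdh1, an epithelial adhesion gene, was lower at -3.92 (-4.60 to -3.35), as were Mgll, Qrfp and Gas7 at -3.01, -2.34 and -2.13. Most treated T cells sat in clusters 9 and 8 (32.8% and 27.6%), and most untreated ones in clusters 26 and 4 (33.1% and 26.5%). Cluster 26 held cells of the untreated library only and may be that library, not a type. Free tumour RNA was measurable, since the epithelial keratin gene Krt8 stood at 218 CPM in untreated T cells, 228 in B cells and 232 in clusters 5, 7, 12 and 18, against 2.57, 1.69 and 5.01 CPM in the treated library. Its part in the list values of these cells, proliferation included, was not tested.

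The inhibitory receptor and exhaustion list in KPB25Luv T cells had 8 of 11 genes higher and 0 lower, with a median of 0.99 (0.69 to 1.22), above all random lists, and Havcr2 at 7.67 against 1.17 CPM. The follicular helper list had 13 of 14 higher and 0 lower, with a median of 1.45 (1.18 to 1.61), above all random lists. Its members Icos, a costimulatory receptor gene, and Il21, a cytokine gene for B cell help, were at 368 against 115 CPM and 5.28 against 0.389 CPM (3.64, 1.88 to 6.83). The activation list had 8 higher and 1 lower of 14, at 0.72 (0.57 to 0.82), with Egr2 at 17.4 against 4.67 CPM. The regulatory list had 6 higher and 0 lower of 12, at 0.48 (0.41 to 0.78), with Tnfrsf4 at 231 against 185 CPM and Tnfrsf18 at 149 against 218 CPM. The cytotoxicity list over all T cells was at 0.16 (-0.07 to 0.33), with Gzma at 65.5 against 8.56 CPM and Nkg7 at 797 against 1045.5 CPM, but at 1.31 (1.04 to 1.79) in cluster 3 and 1.63 (1.32 to 3.64) in cluster 9, against 0.22, 0.35 and 0.16 in clusters 4, 8 and 10, and the naive and memory list at -0.05 (-0.10 to 0.07). The proliferation list had 10 of 20 higher, at 0.60 (0.57 to 0.68), with Rrm2 at 268 against 95.7 CPM, the interferon-gamma list at 0.49 (0.35 to 0.66), the type I interferon list at 0.41 (0.16 to 0.69), and the stress list at 0.61 (0.43 to 0.66). The exhaustion median was 2.49 (1.87 to 3.07) in cluster 3 and -0.27 (-0.83 to 0.19) in cluster 10. In clusters 3 and 10 alone the follicular helper median was 0.29, and the regulatory median turned to -0.05. Cluster by cluster, the follicular helper median was -0.11, 0.63, 0.10, 0.28 and 0.265 in clusters 3, 4, 8, 9 and 10, each under the value over all T cells. The proliferation median was -1.13 (-1.36 to -0.59) in cluster 3 and -1.11 (-1.41 to -0.80) in cluster 4, against 0.65, 0.59 and 0.38 in clusters 8, 9 and 10.

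In KPB25Luv B cells, St7 (133 against 2 UMIs, log2 ratio 3.73, 1.97 to 6.91), the chemokine receptor gene Cxcr4 (2.56, 1.81 to 3.46), Serinc3 (2.20) and Tmem123 (1.97) were higher in the treated library. Cirbp (-1.42, -1.87 to -0.97), Snrnp25 (-1.31), the lymphotoxin gene Ltb (-0.94) and Tomm20 (-0.87) were lower. The B cell activation list had 6 of 12 genes higher and 0 lower, with a median of 0.58 (0.28 to 0.87; 99.96th percentile), and Cd83 at 699.6 against 257 CPM. The antigen presentation list was at 0.41 (0.31 to 0.46; 99.0th percentile), with H2-DMb2 at 0.93 (0.75 to 1.11). The naive list was at 0.21 (0.02 to 0.36), the germinal centre list at 0.25 (-0.29 to 0.93), or 0.12 at its bounds, and the plasma cell programme at -0.00 (-0.28 to 0.41). The interferon-gamma list was at -0.10 (-0.20 to 0.62) and the stress list at 0.73 (0.36 to 0.80).

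In KPB25Luv clusters 5, 7, 12 and 18, with 163 treated and 831 untreated cells, Acod1 was at 125 CPM against 0 UMIs, at least 264-fold higher. The interferon-inducible GTPase gene Iigp1 was at 248 against 2.05 CPM (log2 ratio 6.82, 6.11 to 7.85), Ly6a at 1826 against 44.4 CPM (5.36, 5.18 to 5.55) and Ly6i at 914 against 17.8 CPM. Fcrls was at 2.504 against 264 CPM, the fractalkine receptor gene Cx3cr1 at 10.0 against 261 CPM, and Ltc4s at 3.76 against 79.1 CPM. Plet1 was at 0 UMIs against 45.5 CPM, at least 12.1-fold lower. Treated cells were mostly in cluster 12 (73.0%), and untreated ones in clusters 12 and 7 (55.1% and 42.0%).

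The interferon-gamma response list in these KPB25Luv clusters had 15 of 17 genes higher and 0 lower, with a median of 3.25 (2.84 to 3.32), above all random lists. Cxcl9 was at 210.3 against 8.21 CPM. The type I interferon list had 15 of 15 higher, at 3.45 (3.07 to 3.71), with Isg15 at 508 against 37.4 CPM and Usp18 at 72.6 against 3.16 CPM. The monocyte list was at 1.08 (0.94 to 1.24), with Ly6c2 at 1485 against 143 CPM, and the inflammatory list at 0.87 (0.32 to 1.13), with Ccl4 at 247 against 62.8 CPM. The complement and phagocytosis list had 2 higher and 8 lower of 12, at -1.15 (-1.25 to -0.95), with Spp1 at 593 against 3309 CPM and C1qa at 954 against 3759.9 CPM. The proliferation list had 17 of 20 lower, at -2.51 (-3.05 to -2.10), or -2.29 with 2 genes at their bounds. Free tumour RNA was higher in the untreated cells, with Krt8 at 5.01 CPM in treated and 232 CPM in untreated ones. Its part in that value was not tested. The MHC class II list was at 0.54 (0.30 to 0.59), the stress list at 0.25 (0.14 to 0.35), and the alternative macrophage list at 0.52 (0.20 to 0.82), with Arg1 at 2.29 and Ccl8 at 2.60. The alternative median turned to -0.05 as a mean of per-cell CPM. The median gene of these clusters was at -0.20.

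KPB25Luv epithelial cells, 69 treated and 2879 untreated, were read for the tumour lists. C1s1 was at 80.4 CPM against 1 UMI in the untreated library (log2 ratio 11.37, 9.84 to 17.66), the eosinophil chemokine gene Ccl11 at 285 against 0.325 CPM, Iigp1 at 212 against 0.681 CPM (8.25, 7.83 to 8.77), and the matrix gene Lum at 97.2 against 0.634 CPM. The glutathione transferase gene Gstt1 was at 7.63 against 957 CPM, and Igfbp6 (-6.54), Snai1 (-5.93) and Slc14a1 (-4.51) were lower as well. The tumour interferon-gamma list had 10 higher and 1 lower of 14, with a median of 2.45 (2.19 to 2.56), above all random lists, and Cxcl10 at 273 against 59.9 CPM. The type I interferon list had 15 of 16 higher, at 3.63 (3.34 to 3.80). The MHC class I list had 8 of 14 higher, at 0.73 (0.56 to 0.81), with Tap1 at 75.3 against 10.8 CPM. The extracellular matrix list was at 1.01 (0.78 to 1.26), with Fn1 at 1453 against 625 CPM, and the stress list at 1.20 (0.99 to 1.28). The hypoxia list was at 0.15 (0.10 to 0.63), which turned to -0.00 after centring on the median gene, at 0.15, and the proliferation list was at -0.10 (-0.15 to 0.04). Cluster 24 held 88.4% of the treated and 10.4% of the untreated cells, and within it the interferon-gamma median was 4.56, the extracellular matrix median 2.23 (2.04 to 2.69) and the stress median 0.29 (0.24 to 0.57), while the proliferation median turned to 0.44 (0.39 to 0.54). Cluster 25 held 88.7% of the untreated cells and 1 treated cell. The untreated library also held 298 cells of cluster 24, beside 61 treated ones, so the library alone does not separate these clusters. Values over the class therefore largely compare treated cells of cluster 24 with untreated cells of cluster 25.

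KPB25Luv neutrophils, 57 treated and 785 untreated, had 13 of 13 interferon-gamma genes higher, with a median of 5.21 (4.48 to 5.43) beside a median gene at -0.69. Their marker S100a9 was at -1.67 (-1.82 to -1.53), found in 57.9% of treated and 88.4% of untreated cells, so a different make-up of the class is not excluded. KPB25Luv NK cells were lower for proliferation at -1.36 (-1.74 to -0.91) and higher for stress at 0.93 (0.69 to 1.13). They also held free tumour RNA, with Krt8 at 3.14 CPM in treated and 196 CPM in untreated NK cells. Its part in the proliferation value was not tested. Over all KPB25Luv cells, the lymphoid chemokine and cytokine list was at 1.69 (1.44 to 1.92), with Ltb at 2.60 (2.57 to 2.63), and Cxcl13 at 0 UMIs in the treated library, at least 6.19-fold lower. Values over all cells mix expression with class shares, and within KPB25Luv B cells Ltb was lower at -0.94 (-1.07 to -0.80). Endothelial activation genes could not be compared, with 5 and 9 endothelial cells in the treated libraries.

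**Figure D2:**
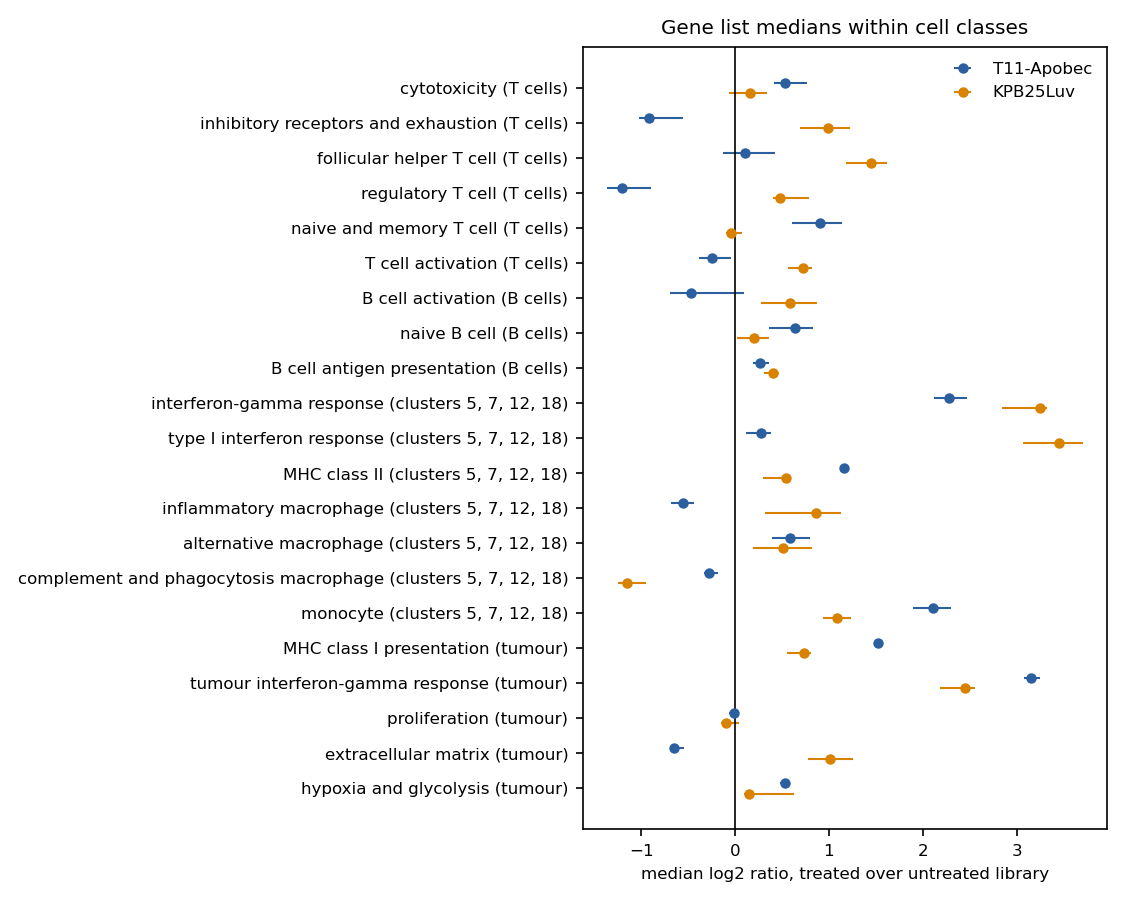
Points give the median log2 ratio of treated over untreated (x axis) for 21 gene lists (y axis, with the cells read) in each model, and lines the 95% counting interval. The interferon-gamma lists shown, of clusters 5, 7, 12 and 18 and of tumour cells, lay between 2.28 and 3.25, while the T cell exhaustion list lay at -0.92 in T11-Apobec and 0.99 in KPB25Luv.

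The genes of the therapy's targets were read in every class. Pdcd1 (ENSMUSG00000026285, GRCm38 chromosome 1, 94038305 to 94052553), the PD1 gene, was at 281 CPM (272 to 290.1) in treated and 281 CPM (243 to 324) in untreated T11-Apobec T cells, and at 82.8 (79.0 to 86.7) against 40.8 CPM (35.5 to 46.8) in KPB25Luv T cells. Ctla4 (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832) was at 51.1 (47.2 to 55.2) against 103 CPM (80.8 to 130.4) in T11-Apobec and 113 (108 to 117) against 37.5 CPM (32.4 to 43.2) in KPB25Luv. In B cells both genes lay at or under 6.02 CPM in all 4 libraries. Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), the PD-L1 gene, was at 32.9 (28.9 to 37.4) against 5.10 CPM (3.86 to 6.61) in T11-Apobec clusters 5, 7, 12 and 18, and at 72.6 (55.1 to 93.9) against 11.8 CPM (9.31 to 14.8) in the KPB25Luv ones. In KPB25Luv neutrophils it was at 900.3 (659 to 1201) against 61.9 CPM (46.5 to 80.8), and in T11-Apobec tumour cells at 2.28 (1.65 to 3.07) against 0.517 CPM (0.3602 to 0.719). Cd86, a ligand of CTLA4, was at 62.2 against 106 CPM in T11-Apobec clusters 5, 7, 12 and 18 and 110.2 against 128 CPM in the KPB25Luv ones. The mouse gene Apobec3 was at 46.3 against 32.1 CPM in T11-Apobec tumour cells.

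**Figure D3:**
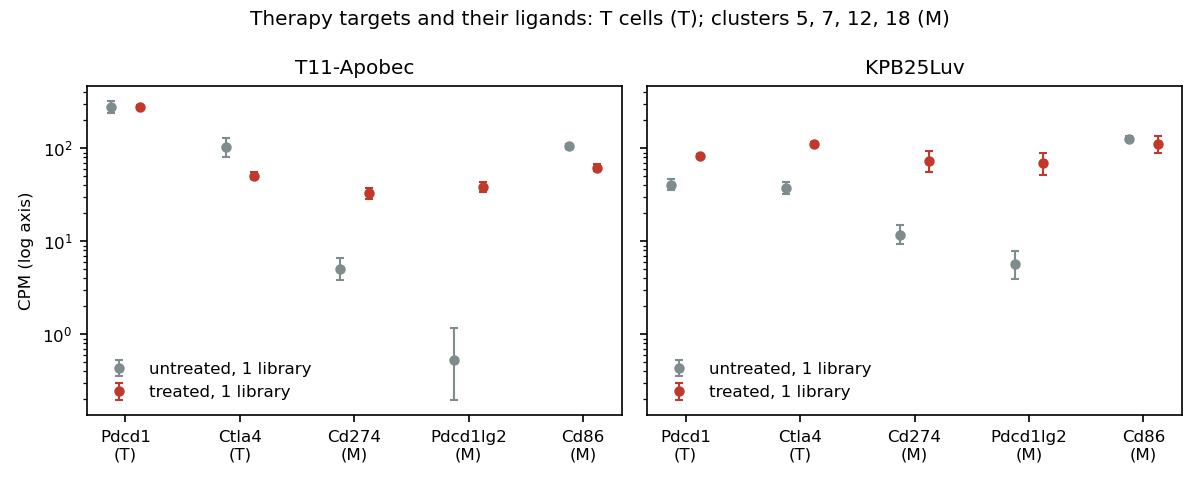
Points give CPM (y axis, log scale) with exact 95% intervals for Pdcd1 and Ctla4 in T cells and Cd274, Pdcd1lg2 and Cd86 in clusters 5, 7, 12 and 18 (x axis), per library. Cd274 was higher in both treated libraries, at 32.9 against 5.10 and 72.6 against 11.8 CPM, while Ctla4 was lower in treated T11-Apobec and higher in treated KPB25Luv T cells.

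Immunoglobulin isotypes were compared within each model. In treated T11-Apobec B and plasma cells, 87.3% (87.0 to 87.6%) of heavy-chain constant region UMIs came from switched genes, against 39.5% (35.9 to 43.1%) in the untreated library. In KPB25Luv the shares were 91.3% (91.1 to 91.5%) and 8.61% (7.10 to 10.3%). Plasma cells carried most of these UMIs in the treated libraries, and in untreated T11-Apobec 1 plasma cell held 276 of 735. In treated plasma cells Ighg1, the IgG1 gene, gave 53.8% of heavy-chain UMIs in T11-Apobec and 86.3% in KPB25Luv, where the IgE gene Ighe gave 10.9%. In B cells alone the switched share was 5.35% (4.73 to 6.02%) against 3.05% (1.68 to 5.06%) in T11-Apobec and 8.29% (7.64 to 8.97%) against 3.78% (2.75 to 5.06%) in KPB25Luv. Ighg1 in B cells was at 130.5 CPM against 0 UMIs in T11-Apobec, at least 7.22-fold higher, and at 198 against 77.8 CPM in KPB25Luv. The same gene stood at 12.7 and 68.0 CPM in the treated T cells, which should lack it, so free RNA carried the gene into other cells. The switched list in B cells had a median of 5.14 in T11-Apobec, or 0.11 at its bounds, and of 2.19 in KPB25Luv, or 1.58 at its bounds. The unswitched list of Ighm and Ighd was at 0.37 (0.21 to 0.54) and 0.35 (0.24 to 0.46).

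T cells were clustered again into subsets. CD8 T cell-like sub-clusters held 37.6% (35.8 to 39.4%) of treated and 35.7% (31.0 to 40.6%) of untreated T11-Apobec T cells. Regulatory T cell-like sub-clusters held 16.8% (15.4 to 18.2%) against 43.7% (38.8 to 48.7%), and naive T cell-like ones 31.9% (30.2 to 33.7%) against 4.22% (2.48 to 6.67%). At resolution 0.5 the regulatory shares became 1.49% and 0.496%, and the naive shares 47.4% and 47.9%, so these orders rest on the resolution. In KPB25Luv the shares were 11.03% (10.1 to 12.1%) against 0.843% (0.405 to 1.55%) for CD8, 15.1% (13.97 to 16.3%) against 4.81% (3.66 to 6.18%) for regulatory, and 20.4% (19.2 to 21.7%) against 36.9% (34.2 to 39.7%) for naive sub-clusters. Of the 438 untreated cells called naive, 417 were in sub-cluster 15, whose leading genes include the tumour genes Krt8, Wfdc2 and Krt18 and which may be that library, not a type. At resolution 0.5 the naive shares became 21.1% and 3.29%. Unnamed sub-clusters held 37.8% of treated and 55.3% of untreated KPB25Luv T cells. Of the untreated ones, 650 were in sub-cluster 13, which was also led by Krt8, Wfdc2 and Krt18. How many of these were CD8 or regulatory T cells cannot be told, so the untreated CD8 and regulatory shares may be too low. Detection of Cd8a and Foxp3 at equal depth, given below, did not show the differences of the CD8 and regulatory shares. The sub-clusters were mostly of 1 library each and may reflect the library.

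At an equal depth of 1000 UMIs, the granzyme gene Gzmb had a UMI in 19.5% (18.1 to 21.1%) of treated and 7.81% (4.90 to 11.7%) of untreated T11-Apobec T cells, beside 0.384% and 0.0766% in clusters 5, 7, 12 and 18. Before thinning, the shares in treated and untreated T cells were 28.9% and 11.9% for Gzmb, and 46.6% and 29.03% for Cd8a. Median depths were 3583 and 1766 UMIs in these T cells and 8795 and 3953 in clusters 5, 7, 12 and 18, and 85 treated and 134 untreated T cells were too shallow. Cd8a was found in 28.0% against 30.9%, and Foxp3, the regulatory T cell factor, in 2.17% (1.67 to 2.78%) against 3.35% (1.54 to 6.26%), neither difference being detectable at this depth. In KPB25Luv, Gzmb was found in 4.24% (3.62 to 4.94%) against 2.51% (1.67 to 3.603%), Cd8a in 23.3% against 25.1%, Foxp3 in 3.09% against 3.31% and Cxcr5 in 2.12% against 0.895%. Median depths there were 4085 and 3622 UMIs, and Cd8a had a UMI in 1.36% and 2.41% of cells of clusters 5, 7, 12 and 18, at 4519 and 7738 UMIs. In those cells Gzmb had a UMI in 0 of 147 treated and 0.127% of untreated cells, and Foxp3 and Cxcr5 in 0 of 147 and 0 of 788, where 3 cells would be 2.04% and 0.381%.

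The third comparison set the models side by side. The models differ in tumour line, mutagenesis and mouse strain together. The log2 ratio of T cell shares was higher in T11-Apobec by 1.43 (1.25 to 1.61), that of B cell shares by 0.69 (0.34 to 1.03), and that of clusters 5, 7, 12 and 18 by 0.89 (0.63 to 1.16). The T cell difference was largely set by the untreated shares, since an untreated share of 38.1% in KPB25Luv capped the ratio there. The treated share itself was lower in T11-Apobec, at 57.4% against 78.1% in KPB25Luv. In those clusters, the T11-Apobec minus KPB25Luv difference of log2 ratios was -0.97 (-1.11 to -0.55) for the interferon-gamma list and -3.17 (-3.48 to -2.75) for the type I interferon list. In cluster 12 alone the interferon-gamma ratios were near level, at 3.16 (2.66 to 3.58) in T11-Apobec and 3.28 (2.88 to 3.50) in KPB25Luv. The T cell follicular helper list differed by -1.35 (-1.63 to -0.85), but in clusters 3 and 10 alone its medians were 0.54 in T11-Apobec and 0.29 in KPB25Luv. In the untreated tumours, T cells were 10.4% of T11-Apobec and 38.1% of KPB25Luv immune cells, neutrophils 4.36% and 25.2%, NK cells 11.8% and 2.60%, and clusters 5, 7, 12 and 18 68.2% and 26.7%. The non-immune cells of T11-Apobec were mostly tumour/mesenchymal, 53.8% of all cells, and those of KPB25Luv mostly epithelial, 47.0%.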

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

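The tests weighed here were chosen only after the result was seen, except the floor, free RNA and dilution tests, which were chosen before the data were examined. Results of opposite sign in the 2 models are listed first, and none of these differences was tested between animals. In T cells the T11-Apobec minus KPB25Luv difference of list medians was -1.905 for inhibitory receptors, -1.684 for regulatory genes, -0.966 for activation and -1.079 for type I interferon genes. These lists did not keep opposite signs in every cluster. Inhibitory receptor medians in T11-Apobec and KPB25Luv were 0.45 and 2.49 in cluster 3 and -0.32 and 1.11 in cluster 4. They were -0.99 and -0.27 in cluster 10. Regulatory medians were 0.68 and 1.16, -0.12 and 2.01, and -0.35 and -0.09 in the same clusters. For both lists the intervals of T11-Apobec in cluster 4 and of KPB25Luv in cluster 10 spanned both signs. Activation medians in T11-Apobec and KPB25Luv were 0.84 and 1.055 in cluster 3, -0.42 and 0.66 in cluster 4, and -0.41 and 0.33 in cluster 10. Type I interferon medians were 1.215 and 1.495, 3.95 and 0.56, and -0.68 and 0.57 in the same clusters. The value of 3.95 rests on 60 untreated cells and has no bound for genes without a UMI, so its size is uncertain. In clusters 5, 7, 12 and 18 the difference of list medians was -1.424 for the inflammatory list and 2.688 for proliferation. In cluster 12 alone the proliferation medians shared a sign, at -1.92 (-2.40 to -1.41) in T11-Apobec and -2.065 (-2.88 to -1.81) in KPB25Luv. The inflammatory medians there were -0.19 (-0.47 to 0.02) and 0.86 (0.28 to 1.17). In epithelial cells the difference was 5.689 for the class share, -4.81 for extracellular matrix and -1.489 for hypoxia genes, where the T11-Apobec cells were all of cluster 21 and the KPB25Luv cells mostly of clusters 24 and 25. The T11-Apobec matrix values ran with free RNA, Col3a1 being at 6.05 against 64.0 CPM in epithelial cells and 4.92 against 52.4 CPM in T cells. The dissociation stress list differed by -1.061 in T cells, -1.21 in B cells, -0.9833 in clusters 5, 7, 12 and 18 and -1.624 in epithelial cells. UMIs of a neomycin resistance gene numbered 1178 in the treated and 3449 in the untreated T11-Apobec library, a difference that was not tested.

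The higher T cell share in treated T11-Apobec tumours was set against losses at the floor of 500 UMIs. After thinning the treated library class by class to the untreated medians, the log2 ratio was 2.41 (2.26 to 2.57; 2632 of 4753 cells), against 2.46 before thinning. The depth of the kept cells thus accounted for little of the difference. The untreated medians leave out cells already under the floor, so the test cannot exclude a loss of such cells. Lymph node or blood carried over with the tumour and infiltration cannot be told apart. Cells of clusters 2 and 3 per cell of clusters 5, 7, 12 and 18 were higher by a log2 ratio of 4.62 (4.37 to 4.87; 1357 against 186 cells) in T11-Apobec and 4.50 (4.10 to 4.90; 426 against 96) in KPB25Luv, which decides nothing, since the denominator is the class whose share differed. For B cells the same stays open, with B cells per cell of cluster 4 at -1.52 (-1.96 to -1.07) in T11-Apobec and 1.16 (0.84 to 1.48) in KPB25Luv.

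Interferon-gamma genes higher in treated T11-Apobec tumour cells were set against free RNA from clusters 5, 7, 12 and 18. Their fraction of the level in those clusters was 245.6 times (203.6 to 282.5) that of the macrophage/monocyte markers, with median fractions of 0.9611 and 0.003914, which excludes that source. Different clusters holding the class and a difference within tumour cells cannot be told apart. The median was -0.14 (-0.23 to 0.02; 537 against 114 cells) within cluster 1, 1.14 (0.72 to 1.64; 103 against 2309) within cluster 14 and 1.135 (0.68 to 1.48; 71 against 448) within cluster 16, and the clusters were formed on the same genes.

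The opposite T cell lists of the models were set against the mix of T cell clusters. With clusters 3, 4 and 10 at equal weight, the inhibitory receptor difference was -1.26 (-1.64 to -0.88; T11-Apobec -0.09, KPB25Luv 1.18), so mix and a difference within clusters cannot be told apart, while the regulatory difference was -0.375 (-0.72 to -0.06; -0.20 and 0.17), in line with a part of it lying in the mix. Free tumour RNA diluting T cell transcripts in untreated KPB25Luv would raise the T cell markers as a set. Over 18 T cell markers the median was 0.23 (0.20 to 0.28), in the direction of dilution but under the inhibitory receptor median of 0.99. That argues against dilution as the whole cause, while dilution as a part of it stays open. The markers may also shift with the mix of T cells. The stress list difference of -1.06 (-1.27 to -0.76) was consistent with handling stress, which may act on both libraries of a model unequally. Strain, mutagenesis and tumour line differ together between the models and stay open as untested.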

How the results depend on the processing

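All alternatives listed before the data were examined were run, and 5 more, 4 by cluster and 1 with the doublet tool's own threshold, were chosen after seeing the data. No test of significance was chosen after the result was seen, since none was made. No paired analysis was possible because each group was 1 library and its replicate number links no animals. A value counted as turned only if its sign changed and the main counting interval excluded 0. Otherwise it counted as held if it lay in that interval and as moved if not. Sign changes of values whose interval included 0 are thus among those held or moved. Of 216 class share values 169 held, 41 moved and 6 turned. Of 933 list medians 733 held, 187 moved and 13 turned, and of 448 values of named genes 396 held, 52 moved and 0 turned. Of 24 sub-cluster values 11 held and 13 moved, of 20 detection values 5 held and 15 moved, and all 8 isotype values moved. The isotype alternatives measured other quantities than the main value, a share of cells or the UMIs of B cells without plasma cells. Plasma cells held 44111 of 48951 heavy-chain UMIs in treated T11-Apobec and 86464 of 93172 in treated KPB25Luv. The cause of the other changes was not tested. Depth limits the treated KPB25Luv neutrophils, where 1 UMI was 19.6 CPM, the untreated T11-Apobec B cells, where it was 6.02 CPM, and the KPB25Luv NK cells, where it was 3.14 and 3.51 CPM.

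With classes from the marker score, the log2 ratio of T cell shares was 2.693 in T11-Apobec and 1.262 in KPB25Luv, that of plasma cells 0.8221 and 2.71, and that of T11-Apobec plasmacytoid dendritic cells -0.0285, while the KPB25Luv epithelial interferon-gamma median was 2.653. Over all kept cells, T cells stood at 3.538 and 1.989, B cells at 2.901 and 2.085, clusters 5, 7, 12 and 18 at -1.055 and -2.064, and T11-Apobec NK cells at 0.5041. A floor of 500 genes gave 3.106 for T11-Apobec B cells and 0.8999 for KPB25Luv T cells. A limit of 20% mitochondrial UMIs gave -2.319 and -3.693 for clusters 5, 7, 12 and 18. Keeping doublets gave 0.7513 and 0.2962 for fibroblasts. With each library clustered alone, KPB25Luv T cells stood at 1.449, the macrophage/monocyte class at -3.322, endothelial cells at 0.2081, fibroblasts at 0.2826 and epithelial cells at -8.307.

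As a mean of per-cell CPM, the KPB25Luv medians were 0.6259 for exhaustion, 0.3854 for regulatory and -0.0511 for alternative macrophage genes, and the tumour interferon-gamma medians 3.009 in T11-Apobec and 2.082 in KPB25Luv. Thinned to 1000 UMIs, the KPB25Luv exhaustion median was 0.6311, the regulatory medians -0.559 in T11-Apobec and 0.173 in KPB25Luv, the tumour interferon-gamma medians 2.843 and 1.992, the KPB25Luv interferon-gamma median in clusters 5, 7, 12 and 18 2.823, and the T11-Apobec proliferation median there -0.04209. Without immunoglobulin, ribosomal and mitochondrial genes in the total, the KPB25Luv regulatory median was 0.3843 and the hypoxia median -0.003065. Centring on the median gene gave 0.3951 and -0.001218 for these, and 3.448 for interferon-gamma genes in clusters 5, 7, 12 and 18.

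In clusters 3 and 10 only, the T11-Apobec medians were -0.2512 for cytotoxicity, 0.05625 for exhaustion, 0.5419 for follicular helper, 0.1548 for regulatory, 0.2898 for activation and 0.4991 for type I interferon genes, and the KPB25Luv ones 0.2866 for follicular helper and -0.04967 for regulatory genes. In cluster 12 only, the T11-Apobec medians were 3.159 for interferon-gamma, -0.8479 for MHC class II, 0.5325 for complement and -1.921 for proliferation genes. The tumour interferon-gamma median was 1.243 in clusters 14 and 16 and 4.559 in cluster 24.

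Switched genes were the most abundant in 6.34% of treated and 2.532% of untreated T11-Apobec cells with a heavy-chain UMI, and in 15.78% and 3.488% of KPB25Luv ones. In B cells only, the switched share of UMIs was 5.351% and 3.05% in T11-Apobec and 8.289% and 3.779% in KPB25Luv. At a sub-cluster resolution of 0.5, the treated T11-Apobec shares were 39.46% CD8, 1.486% regulatory and 47.41% naive, and the untreated ones 0.4963% regulatory and 47.89% naive. The KPB25Luv regulatory shares were 21.26% treated and 6.324% untreated, and the untreated naive share 3.288%. At resolution 2, the naive share was 18.38% in treated and 2.233% in untreated T11-Apobec and 31.79% in untreated KPB25Luv, and the untreated regulatory shares were 38.46% and 6.239%.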

Other observations

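No tests are reported here, and the gene was chosen only after the result was seen. The neomycin resistance gene was read at 57.8 CPM (54.4 to 61.3) in treated and 44.0 CPM in untreated T11-Apobec tumour cells. Within clusters the values were 40.1 against 42.4 in cluster 1, 18.6 against 18.7 in cluster 14, 85.1 against 40.75 in cluster 15 and 237 against 214 in cluster 16. KPB25Luv libraries held 0 UMIs of it.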
